A study of Mus musculus with 8 samples.

How the data were processed

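RNA-seq was performed on mouse regulatory T cells (Treg), the CD4 T cells that express the transcription factor Foxp3 and restrain other immune cells. Per the labels' protocols, CD4+ cells carrying the YFP reporter were sorted by flow cytometry directly after spleen and peripheral lymph nodes were taken from untreated C57BL/6 mice. The mice carried 1 copy of a Foxp3 allele that makes YFP and Cre recombinase, together with either 2 loxP-flanked copies of Pdpk1 or 2 unmodified copies. The series holds 8 libraries in 2 groups of 4, called WT and labelled Pdpk1 KO below, numbered as in the labels. Pdpk1 encodes PDK1, the kinase that phosphorylates AKT and related kinases downstream of PI3K. It is a different gene from Pdk1, which encodes a mitochondrial pyruvate dehydrogenase kinase. Polyadenylated RNA was extracted with the RNeasy Plus Micro kit and libraries were made with the NEBNext Ultra II RNA kit. The labels do not say whether each library came from 1 mouse, so p-values measure the spread between these libraries.

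The deposited table held 1 signal value per gene and library, gene read counts that the authors divided by a DESeq2 size factor. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.6a, SAMtools 1.11, featureCounts from Subread 2.0.1, DESeq2 1.21 and the build GRCm38. The notes list these without roles or settings, and the strand setting and annotation release were not given in the sources used here. Without a stated strand, reads of overlapping or antisense genes cannot be told apart. The counting of reads shared by near-identical copies was also not given, so values of the Gbp, Naip and H2-Q genes, the ribosomal proteins and Atp6v0c, which have close copies or pseudogenes, are uncertain in that respect.

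In each library 100% of the values were whole multiples of the smallest positive value within a tolerance of 0.001, so whole reads and depth could be recovered. The recovered reads came to between 17448095 and 26299577 per library. The table listed 19826 Ensembl genes, of which 19775 matched a symbol in GENCODE release M21 and 51 did not. The smallest total of any listed gene was 11 reads over the libraries, so genes with fewer reads were not analysed here. Gene positions are those of GENCODE M21 on GRCm38. A value of 0 in a library allows up to 3 reads, equal to normalized counts between 2.56 and 3.38 depending on the library, for counting error only. PCR duplicates are not marked by molecular identifiers in these values.

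Genes were tested when at least 4 of the 8 libraries had a normalized count of 10 or more. That left 13847 genes and removed 5979. Values were transformed as log2(normalized count + 1) and compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No replicate term was used. All log2 changes and folds are on the log2(normalized count + 1) scale, which understates the change of low genes, and are given as the libraries labelled Pdpk1 KO minus WT. An adjusted p without another tool's name is from this fit. Single values (the targeted gene, Foxp3, Xist and 7 library measures) were also compared by an exact two-sided permutation test over the 70 assignments of the libraries, whose smallest possible p is 0.0286. The 7 library measures were adjusted together.

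The test, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. The lists were written from general knowledge of T cells. Of these, 28 had at least 3 tested members and were compared with camera from limma, which asks whether a list's genes move relative to all other genes, using the preset correlation of 0.01 between genes. Camera with a correlation estimated from these libraries was run beside it. The fry test, which asks whether a list's genes move on balance in 1 direction without reference to other genes, was also run. Several lists share members, for example Itgae, Ccr2 and Cxcr3, so their results are not independent. The named genes were Pdpk1 and Foxp3, then the 8 largest rises and 8 largest falls. Those needed an adjusted p under 0.05, an absolute log2 change of at least 1, a mean normalized count of at least 50, an established symbol and groups that do not overlap. Of each list, up to 4 members past the threshold with the smallest adjusted p were named, or the 2 with the highest mean where none passed. Other genes named below were chosen after their values were seen. Some genes that the rule selects are not reported here, and the list counts include them. Lists of 19 macrophage markers and 12 markers of recent thymic emigrants, and 14 gene families defined by symbol, were also written after the data had been examined.

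The limma, edgeR and DESeq2 steps were tested on simulated counts for the 13847 genes of this comparison, with 50 genes changed at each fold. The limma step recovered 42% of the genes changed 1.5-fold, 66% at 2-fold, 84% at 4-fold and 84% at 8-fold, and 6.02% of its calls were false. The edgeR step recovered 42%, 64%, 86% and 84% with 6.59% false calls. The DESeq2 step recovered 48%, 70%, 88% and 90% with 16.2% false calls. A simulated list of 20 raised genes was called and 0 of the 28 lists besides. The genes were simulated independently of each other, whereas the correlation estimated in the libraries reached 0.926 for ribosomal proteins. The simulation therefore does not show how often lists of correlated genes are called falsely.

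Alternatives covered pseudocounts of 0.5 and 5, no filter, a filter at a mean of 50, TMM rescaling, quantile normalization, sample quality weights, the replicate number as a block, and leaving out each library. Counts were also made with an absolute log2 change of at least 1. On the recovered reads, the quasi-likelihood test of edgeR 4.0.16 called 1254 genes and the Wald test of DESeq2 1.42.0 called 1756, against 1311 in the limma fit. Of the tested genes, 269 had no adjusted p in DESeq2 and were left out of its counts. After the data had been examined, 4 alternatives were added. They were the macrophage marker mean as a covariate, the comparison without the 3 libraries highest in those markers, a correction for transcript GC content and length, and the counts without genes within 20 Mb of Pdpk1.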

Results

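The series asked how loss of PDK1 changes the transcriptome of regulatory T cells in mice that carry the Foxp3 YFP-Cre allele on 1 X chromosome, where Cre-expressing Treg share the animal with Treg that lack Cre. Polyadenylated RNA of sorted CD4+ YFP+ cells from spleen and peripheral lymph nodes was sequenced in 4 WT libraries and 4 libraries labelled Pdpk1 KO. Depth was 21201000 ± 2960000 recovered reads in WT and 22643000 ± 2711000 in the libraries labelled Pdpk1 KO (SD, n = 4 each), from 17448095 to 26299577 over all. Across the 13847 genes tested, correlations of log2 values lay between 0.944 and 0.968 within groups and between 0.925 and 0.955 across groups. The first principal component, with 31.5% of the variance, placed the 4 WT libraries between -54.6 and -27.5 and the 4 labelled Pdpk1 KO between 25.8 and 52.2. No pair of replicates agreed within counting noise, the chi-square per degree of freedom being 14.5 or more in every pair.

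Pdpk1 itself (ENSMUSG00000024122, chromosome 17, 24073680 to 24150924, minus strand, protein coding) was not detectably lower at the level of the whole gene. Its normalized counts were 2599.6, 2374.4, 1995 and 1923.3 in WT replicates 1 to 4. They were 2505.5, 1900.1, 1871.5 and 1656.4 in replicates 1 to 4 labelled Pdpk1 KO. The log2 change was -0.17 (95% interval -0.452 to 0.111, exact permutation p = 0.286, limma adjusted p = 0.491). Reads over all exons are summed in this value, and the exons flanked by loxP were not given in the sources used here, so it does not check the labels, and the groups are called by their labels throughout. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245, plus strand), the factor that defines Treg, stood at 5086 ± 740 normalized counts in WT and 5355 ± 743 in the libraries labelled Pdpk1 KO (SD, n = 4 each, exact permutation p = 0.6). The log2 difference was 0.08 (95% interval -0.178 to 0.328). Xist, transcribed from the inactive X chromosome, had 5084.5 or more normalized counts in every library (exact permutation p = 0.486 between groups). The Y-linked genes Eif2s3y, Uty and Ddx3y had 14, 14 and 15 reads in total over the 8 libraries.

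Of the 13847 genes, 611 were higher and 700 lower in the libraries labelled Pdpk1 KO, together 9.47% of those tested. With an absolute log2 change of at least 1 the counts were 154 and 327. All 4 values of 1 group lay beyond all 4 of the other for 543 of the higher and 658 of the lower genes. Over all tested genes this held for 15.3%, where chance gives 2.86%. DESeq2 called 848 higher and 908 lower. In limma the count of higher genes was 389 without WT replicate 4 and 395 without replicate 3 labelled Pdpk1 KO. With the replicate number as a block, which the labels do not show to pair libraries, limma called 1243 higher and 1292 lower. Markers of macrophages also stood higher on average in the libraries labelled Pdpk1 KO (values below). With their mean level as a covariate, 213 genes were higher and 280 lower.

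Several of the largest falls were in genes of effector T cells. Gzmb, which encodes the cytotoxic protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), went from 333 ± 136 normalized counts in WT to 10.2 ± 12.1 in the libraries labelled Pdpk1 KO (SD, n = 4 each), a log2 change of -5.42 ± 0.60 (SE, adjusted p = 3.56e-05). The opioid precursor gene Penk fell from 749 ± 196 to 33.8 ± 13.7 normalized counts, and the gene of the suppressive cytokine interleukin 10, Il10, from 122 ± 69.8 to 7.70 ± 7.71. The receptor gene Klrg1, a marker of terminally differentiated effector cells, went from 215 ± 75.2 to 18.4 ± 20.1. The chemokine receptor gene Ccr2 fell from 786 ± 258 to 53.3 ± 11.7, a log2 change of -3.83 ± 0.24 (SE, adjusted p = 3.46e-07). Igsf9b, of the immunoglobulin superfamily, and the gap junction gene Gjb2 also fell, at log2 changes of -4.07 and -4.05, each with 1 library at 0 in the group labelled Pdpk1 KO. With the macrophage covariate Il10, Igsf9b and Gjb2 were at -2.90, -2.66 and -3.82 and not past the threshold (adjusted p = 0.0784, 0.207 and 0.126). The largest rises were in genes with low counts in WT. Kirrel, an adhesion molecule gene, was listed at 0 in 3 WT libraries and 7.89 in WT replicate 1, against 112.27 to 243.27 normalized counts in the libraries labelled Pdpk1 KO. The amino acid transporter gene Slc6a19 went from 4.17 ± 4.82 to 130 ± 49.9, and the calsyntenin gene Clstn3 from 9.35 ± 6.65 to 130 ± 42.0. Sema7a, a membrane-anchored semaphorin gene, rose from 80.5 ± 22.9 to 583 ± 155 (log2 change 2.85 ± 0.24 SE, adjusted p = 3.11e-06). Cyp26b1, encoding an enzyme that degrades retinoic acid, rose from 20.9 ± 7.13 to 176 ± 62.0. The prohormone convertase gene Pcsk1, the protease gene Prss12 and Ms4a4a rose by log2 changes of 3.03, 2.83 and 2.79. Pcsk1 was at 2.94 and not past the threshold with the macrophage covariate (adjusted p = 0.071), nor without the 3 libraries highest in these markers (3.19, adjusted p = 0.0667).

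**Figure D1:**
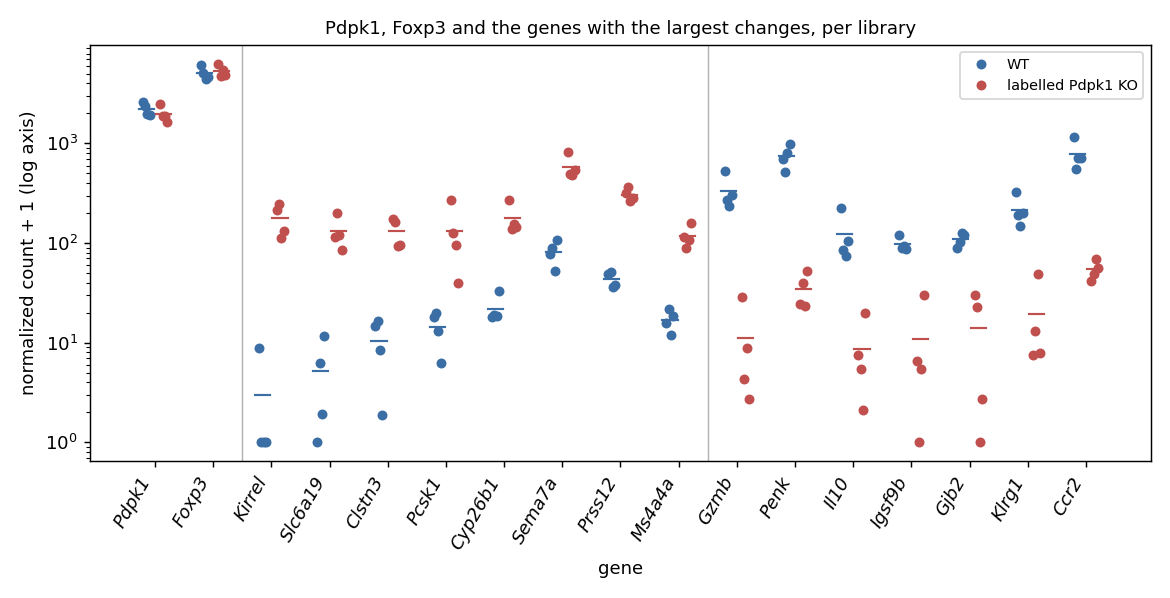
Normalized count + 1 (log axis) of Pdpk1, Foxp3, the 8 largest rises and 7 of the 8 largest falls in the 4 WT libraries (blue) and the 4 labelled Pdpk1 KO (red), 1 point per library, with bars at the group means. The groups overlap for Pdpk1 and Foxp3 and are separate for the other 15 genes, with Gzmb at 332.88 in WT and 10.196 in the libraries labelled Pdpk1 KO on average.

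Genes of Treg identity and suppression fell in part. Of 28 tested members, 18 were lower, 3 higher and 7 not past the threshold (adjusted over the list alone, 21 lower and 4 higher). The median log2 change was -0.64 (camera adjusted p = 4.08e-13). Itgae, encoding the CD103 integrin chain (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), fell from 2424 ± 739 to 214 ± 47.7 normalized counts, a log2 change of -3.47 ± 0.20 (SE, adjusted p = 1.84e-07). Ikzf2, encoding the transcription factor Helios, went from 9041 ± 940 to 4116 ± 379, and Cd83 from 1577 ± 43.5 to 562 ± 114. The 3 that rose were Socs2, a gene induced by cytokines that act through STAT5, from 2018 ± 165 to 4847 ± 693, the interleukin 2 receptor gene Il2ra at a log2 change of 0.63, and Gpr83 at 0.60. Of the effector Treg markers, 24 of 31 tested members were lower, 0 higher and 7 not past the threshold (adjusted over the list alone, 28 lower and 0 higher). Their median log2 change was -1.80 (camera adjusted p = 4.19e-32). Besides Itgae and Ccr2, they included the transcription factor gene Maf, from 6527 ± 1215 to 1298 ± 340, and the inhibitory receptor gene Pdcd1, from 1451 ± 199 to 456 ± 37.5 normalized counts. With an estimated correlation both lists remained past the threshold, at adjusted p = 0.0144 for identity and 0.0127 for effector markers.

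Receptors that guide cells into tissues were lower as a list, with 14 of 26 members lower, 2 higher and 10 not past the threshold (adjusted over the list alone, 16 and 2). The median log2 change was -0.77 (camera adjusted p = 2.21e-09, and adjusted p = 0.0144 with an estimated correlation). The follicle-homing receptor gene Cxcr5 fell by 2.17 and the hyaluronan receptor gene Cd44 by 1.04 on the log2 scale. Among the members that rose was Ccr7, at a log2 change of 0.42, whose product directs T cells into lymph nodes. Genes of effector T helper cells gave 9 of 19 tested members lower, 1 higher and 9 not past the threshold (adjusted over the list alone, 12 lower and 2 higher), with a median log2 change of -1.07. The list's camera adjusted p was 7.84e-08, and adjusted p = 0.0144 with an estimated correlation. Il18r1, a subunit of the interleukin 18 receptor, fell from 1904 ± 83.3 to 731 ± 28.0 normalized counts. The chemokine receptor gene Cxcr3 fell from 881 ± 99.3 to 146 ± 68.1. The member that rose was Il4, at a log2 change of 2.19.

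Markers of naive and central T cells rose, with 11 of 21 members higher, 1 lower (Id3, -0.81) and 9 not past the threshold (adjusted over the list alone, 13 higher and 2 lower). The median log2 change was 0.49 (camera adjusted p = 7.84e-08, and adjusted p = 0.0457 with an estimated correlation), 0.262 with the macrophage covariate and 0.403 without the 3 libraries highest in these markers. The interleukin 7 receptor gene Il7r rose from 2627 ± 637 to 7086 ± 2180 normalized counts, a log2 change of 1.42 ± 0.21 (SE, adjusted p = 0.000437), the survival gene Bcl2 from 8570 ± 376 to 12825 ± 384, and Igfbp4 from 11343 ± 1346 to 20236 ± 2116. FoxO1 is a transcription factor that AKT keeps out of the nucleus. Of 21 genes listed as its targets, 10 were higher, 2 lower (Sesn3 and Ddit4) and 9 not past the threshold (adjusted over the list alone, 13 higher and 3 lower). The camera adjusted p was 1.94e-06, but adjusted p = 0.25 with an estimated correlation. Their median log2 change of 0.42 was 0.245 with the macrophage covariate and 0.361 without the 3 libraries. The pro-apoptotic gene Bcl2l11 rose from 1726 ± 161 to 3530 ± 681 and the insulin receptor substrate gene Irs2 from 342 ± 83.5 to 704 ± 72.4. Il7r belongs to both lists.

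**Figure D2:**
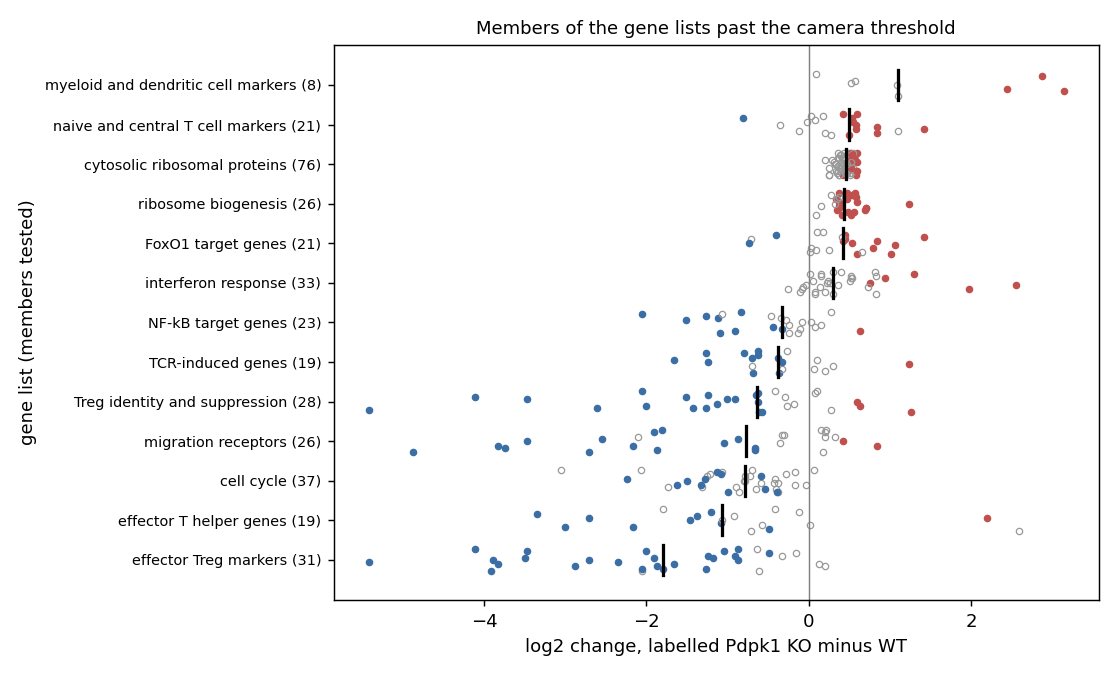
Log2 change (libraries labelled Pdpk1 KO minus WT, log2(normalized count + 1) scale, x axis) of every tested member of the 13 gene lists past the camera threshold (y axis, number of members in brackets). Red points are members past the adjusted threshold and higher, blue points past it and lower, open points not past it, and black bars list medians, which run from -1.80 for effector Treg markers to 1.09 for myeloid and dendritic cell markers.

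Genes induced through the T cell receptor were lower as a list, while Myc rose. Of 19 members, 11 were lower, 1 higher and 7 not past the threshold (the same numbers adjusted over the list alone, 11 and 1), with a median log2 change of -0.38. The camera adjusted p was 7.29e-06, and adjusted p = 0.0144 with an estimated correlation. Tnfrsf9, encoding the costimulatory receptor 4-1BB, fell from 2222 ± 273 to 932 ± 166 normalized counts, and the costimulatory receptor gene Icos from 1144 ± 101 to 494 ± 120. Myc, encoding a transcription factor of cell growth (chromosome 15, 61985391 to 61990374), rose from 3753 ± 150 to 8809 ± 822, a log2 change of 1.23 ± 0.09 (SE, adjusted p = 1.27e-06). Targets of NF-kB gave 9 of 23 lower, 1 higher (Il2ra) and 13 not past the threshold (adjusted over the list alone, 14 lower and 2 higher). Their median log2 change was -0.33 (camera adjusted p = 6.14e-07, and adjusted p = 0.0329 with an estimated correlation). The survival gene Bcl2l1 fell by 1.12 and the NF-kB inhibitor gene Nfkbie by 0.83 on the log2 scale. Among 14 tested genes of ERK feedback, Myc, Spry1 and Spred1 rose, the last 2 by log2 changes of 0.86 and 1.09, while Egr3 fell by 0.79 (adjusted over the list alone, 3 higher and 1 lower). Egr3 was at -0.38 with the macrophage covariate and -0.47 without the 3 libraries highest in these markers, not past the threshold (adjusted p = 0.454 and 0.31). That list was not past the threshold in camera (adjusted p = 0.103) but was higher in fry (adjusted p = 0.0367).

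Most ribosome biogenesis genes rose. Of 26 ribosome biogenesis genes, 20 were higher, 0 lower and 6 not past the threshold (adjusted over the list alone, 24 and 0). The median log2 change was 0.43 (camera adjusted p = 1.54e-18, and adjusted p = 0.0329 with an estimated correlation). Besides Myc, the nucleolar protein gene Nop56 went from 2590 ± 114 to 3849 ± 162 normalized counts, Dkc1, encoding dyskerin, from 1935 ± 148 to 3156 ± 407, and Nob1 from 1249 ± 76.4 to 1865 ± 140. Of 76 cytosolic ribosomal protein genes, 19 were higher and 57 not past the threshold over all genes tested (adjusted over the list alone, 54 higher). The camera adjusted p was 7.13e-21, but adjusted p = 0.333 with an estimated correlation, and the median log2 change of 0.46 was 0.153 after quantile normalization, 0.18 with the macrophage mean as a covariate and 0.346 without the 3 libraries highest in these markers (fry adjusted p = 0.0858). Rpl3, Rpl10a, Rps6 and Rpl5 rose by log2 changes of 0.59, 0.57, 0.60 and 0.60. Under quantile normalization Rpl3 and Rps6 were at 0.25 and 0.22 and no longer past the threshold, and Rpl5 lost its call without replicate 2 or replicate 3 labelled Pdpk1 KO (adjusted p = 0.0545 and 0.0604). With the macrophage covariate the 4 were at 0.53, 0.42, 0.37 and 0.32 and without the 3 libraries at 0.53, 0.48, 0.49 and 0.47, not past the threshold. The share of reads from ribosomal protein genes was 11.9 ± 1.73% in WT and 15.3 ± 1.96% in the libraries labelled Pdpk1 KO (SD, n = 4 each, exact permutation p = 0.0857, adjusted p = 0.2 over 7 library measures). Of 37 cell cycle genes, 11 were lower, 0 higher and 26 not past the threshold (adjusted over the list alone, 19 and 0), with a median log2 change of -0.79. The camera adjusted p was 1.16e-11, but adjusted p = 0.25 with an estimated correlation. The median was -0.50 without WT replicate 1, -0.36 with the macrophage covariate and -0.864 without the 3 libraries highest in macrophage markers. Tyms and Rrm2, which supply nucleotides for DNA synthesis, fell by 1.33 and 1.08, the mitotic gene Birc5 by 1.63 and the replication helicase gene Mcm5 by 0.59 on the log2 scale. With the macrophage covariate they were at -1.26, -0.69, -1.37 and -0.47 and not past the threshold (adjusted p = 0.0599, 0.327, 0.146 and 0.169). Without the 3 libraries Rrm2, Birc5 and Mcm5 kept changes of -1.02, -1.54 and -0.60 but were not past it (adjusted p = 0.171, 0.0508 and 0.093).

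Components of the PI3K and PDK1 pathway did not move as a list (camera adjusted p = 0.8), with 6 of 33 higher, 2 lower and 25 not past the threshold (adjusted over the list alone, 6 and 4). The kinase gene Sgk3 rose from 487 ± 46.6 to 749 ± 44.4 normalized counts. Pik3ip1, which encodes an inhibitor of PI3K, rose by a log2 change of 0.79 and the kinase gene Prkcq by 0.39. With the macrophage covariate Pik3ip1, Prkcq and Sgk3 were at 0.38, 0.36 and 0.59 and not past the threshold (adjusted p = 0.415, 0.166 and 0.0902), nor were Pik3ip1 and Prkcq without the 3 libraries highest in these markers, at 0.68 and 0.35 (adjusted p = 0.125 and 0.282). Pik3cd and Rictor also rose, while Inpp5d and Sgk1 fell by 0.31 and 0.68. Of 17 genes of amino acid supply and the ATF4 response, 4 were higher and 2 lower (Mthfd2 and Ddit4), with the same counts adjusted over the list alone (camera adjusted p = 0.331). Trib3, which encodes a pseudokinase that binds AKT, went from 89.7 ± 18.6 to 509 ± 53.2 (log2 change 2.51 ± 0.20 SE, adjusted p = 1.64e-06). Shmt2, Slc38a2 and Slc7a5 rose by 0.76, 0.51 and 0.55. Slc38a2 and Slc7a5 were at 0.51 and 0.50 with the macrophage covariate, not past the threshold (adjusted p = 0.0932 and 0.156). Nor was Slc7a5 past it without the 3 libraries, at 0.57 (adjusted p = 0.0888).

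Most metabolic genes were not past the threshold. Among 22 glycolysis genes, Pdk1 and Eno1 rose by log2 changes of 0.49 and 0.44 and the lactate exporter gene Slc16a3 fell from 337 ± 71.0 to 173 ± 53.6 normalized counts (adjusted over the list alone, 2 higher and 1 lower, camera adjusted p = 0.801). Among 24 cholesterol synthesis genes, 2 were higher and Ebp fell by 0.49 (adjusted over the list alone, 2 higher and 1 lower, camera adjusted p = 0.432). Among 11 fatty acid synthesis genes, Fasn and Acsl3 rose by 0.46 and 0.72 (adjusted over the list alone, 4 higher and 2 lower, camera adjusted p = 0.209, fry adjusted p = 0.0472). Of 20 antioxidant genes, Gclc and Nfe2l2 rose by 0.57 and 0.43 (adjusted over the list alone, 2 higher, camera adjusted p = 0.597). Several of these calls were close to the threshold. Eno1, Ebp, Fasn and Nfe2l2 each lost theirs when any 1 of 4 libraries was left out, with adjusted p up to 0.0764, 0.0838, 0.0849 and 0.0574, while their log2 changes stayed at 0.36 to 0.52, -0.57 to -0.39, 0.37 to 0.55 and 0.37 to 0.48. Acsl3 lost its call without any 1 of 6 libraries (up to 0.127), in edgeR (adjusted p = 0.0525) and with sample quality weights (adjusted p = 0.0596). Slc16a3 lost its call without WT replicate 3 or 4 (adjusted p = 0.068 and 0.0701). With the macrophage covariate Eno1 and Acsl3 were at 0.25 and 0.32 and without the 3 libraries at 0.37 and 0.74, not past the threshold (adjusted p = 0.459, 0.637, 0.36 and 0.191). None of 57 oxidative phosphorylation genes passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.725, median log2 change 0.02). Cox4i1 stood at 6233 ± 1152 and 6503 ± 964 normalized counts and Sdha at 6156 ± 445 and 6482 ± 368 in WT and in the libraries labelled Pdpk1 KO. None of 22 iron handling genes passed either, over all genes or adjusted over the list alone (camera adjusted p = 0.103), with Fth1 and Pcbp1 at log2 differences of -0.05 and 0.18.

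The interferon response list was higher in camera with the preset correlation, with few members past the threshold. Of 33, 5 were higher, 0 lower and 28 not past the threshold (adjusted over the list alone, 5 and 0). The camera adjusted p was 7.07e-06, but adjusted p = 0.463 with an estimated correlation (fry adjusted p = 0.165). Its median log2 change of 0.29 was 0.17 without WT replicate 4, 0.64 with the macrophage covariate and 0.61 without the 3 libraries highest in these markers. Gbp2, Gbp3 and Gbp7, neighbouring guanylate-binding protein genes on chromosome 3 that interferons induce, rose by log2 changes of 1.97, 1.29 and 0.75, and Gbp2 reached 11915 ± 2507 normalized counts from 3015 ± 443. The others were Oasl2 at 0.94 and Ifi44 at 2.56, and Oasl2 lost its call without any 1 of 4 libraries, with adjusted p up to 0.0898. Of 18 cell death and survival genes, 4 rose and 1 fell (adjusted over the list alone, 5 and 3, camera adjusted p = 0.174, fry adjusted p = 0.0367). They were Bcl2, Bcl2l11, Casp8 and Bbc3, the last by a log2 change of 0.63, and Bcl2l1, which fell. Bbc3 lost its call without any 1 of 4 libraries (adjusted p up to 0.0701), with the macrophage covariate (0.17, adjusted p = 0.679) and without the 3 libraries highest in these markers (0.61, adjusted p = 0.107).

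Among markers of other cell types, those of myeloid cells were higher. Of 8 tested, 3 rose and 5 did not pass (adjusted over the list alone, 3 higher). The median log2 change was 1.09 (camera adjusted p = 0.00377, but adjusted p = 0.333 with an estimated correlation). The median was 0.50 without replicate 2 labelled Pdpk1 KO and 1.89 without replicate 1 of that group (fry adjusted p = 0.108 with all libraries). Fcgr3 went from 10.3 ± 7.77 to 85.7 ± 29.5 normalized counts, the lysozyme gene Lyz2 from 50.7 ± 52.5 to 314 ± 212, and Csf1r, encoding the macrophage growth factor receptor, from 88.5 ± 81.8 to 433 ± 317. Csf1r was past the threshold in limma (adjusted p = 0.0282) and not in DESeq2 (adjusted p = 0.0616), nor without any 1 of 5 libraries (adjusted p up to 0.104). The mean log2 level of 17 measured macrophage markers was 4.77 ± 1.30 in WT and 6.91 ± 1.10 in the libraries labelled Pdpk1 KO (SD, n = 4 each, exact permutation p = 0.0857, adjusted p = 0.2 over 7 library measures). It was highest in replicates 2 and 3 labelled Pdpk1 KO, at 8.07 and 7.62, and in WT replicate 2, at 6.51. Without those 3 libraries, 167 genes were higher and 305 lower. That fit holds only WT replicates 1, 3 and 4 and replicates 1 and 4 labelled Pdpk1 KO. Part of the drop can come from fewer libraries, and no other set of 3 was left out for comparison.

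Of 9 B cell markers, Cd79b and Cd22 were lower, at 367 ± 73.1 against 165 ± 43.7 and 54.9 ± 35.6 against 8.34 ± 6.72 normalized counts, and 0 were higher (adjusted over the list alone, 2 lower, camera adjusted p = 0.557). Cd22 lost its call without WT replicate 1 (adjusted p = 0.0656), with the macrophage covariate (log2 change -1.56 against -2.69, adjusted p = 0.418) and without the 3 libraries highest in these markers (-2.18, adjusted p = 0.145). Of 8 markers of CD8 T and NK cells, the cytotoxic granule gene Nkg7 fell by 2.29 on the log2 scale and 7 did not pass (adjusted over the list alone, 1 lower, camera adjusted p = 0.943). Of 3 measured erythroid and stromal markers, Pecam1 rose by 0.36 (adjusted over the list alone, 1 higher, camera adjusted p = 0.557), a call lost without any 1 of 4 libraries (adjusted p up to 0.0938). Mitochondrially encoded genes did not differ past the threshold in limma, 0 of 11 over all genes or adjusted over the list alone (camera adjusted p = 0.619). They took 2.19 ± 0.225% of reads in WT and 2.15 ± 0.253% in the libraries labelled Pdpk1 KO (SD, n = 4 each). The log2 differences of mt-Co1 and mt-Cytb were 0.08 and 0.10, and mt-Cytb was at -0.08 under quantile normalization. Of 13 dissociation and stress genes, Jun rose from 427 ± 127 to 2459 ± 430 normalized counts, a log2 change of 2.56 ± 0.19 (SE, adjusted p = 1.39e-06), Dusp1 fell by 0.54 and 11 did not pass (adjusted over the list alone, 1 higher and 1 lower, camera adjusted p = 0.557).

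**Figure D3:**
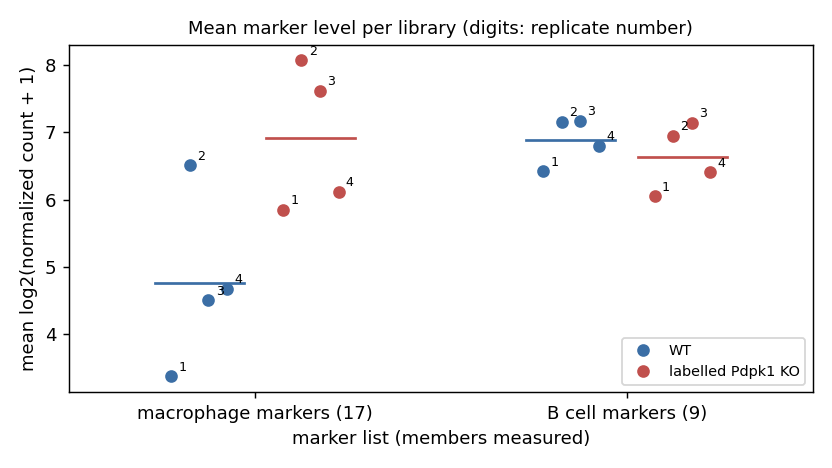
Mean log2(normalized count + 1) of 17 macrophage markers and 9 B cell markers (y axis) in each WT library (blue) and each library labelled Pdpk1 KO (red), with the replicate number beside each point and bars at the group means. The macrophage mean is 4.7652 in WT and 6.9126 in the libraries labelled Pdpk1 KO with overlapping values, and the B cell means lie between 6.047 and 7.174 over all libraries.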

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

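The tests of dilution, macrophage RNA and chromosome 17 were chosen after the results had been seen. The counts of splits were planned, except those with an estimated correlation and of the effector list alone.

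Chance in the grouping of the libraries was examined by splits. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 611 genes in a direction. Likewise 1 gave as many as 700, while the highest of the other splits was 1 gene. A share of 1 in 35 is the smallest these splits can give. Any real group difference also widens the spread within the other splits, which by itself lowers their calls. The real split thus ranked first, and the size of the gap is not further evidence against chance. For the number of gene lists the real split did not stand apart with the preset correlation, since 9 of the 35 splits gave 13 lists or more and the highest other gave 16. With an estimated correlation the real split gave 8 lists and the highest other 0, so only 1 of the 35 splits reached that number. The same limit holds for that gap. The 8 were Treg identity, effector Treg, naive and central, effector T helper, ribosome biogenesis, T cell receptor, NF-kB and migration. For the effector Treg list alone, 1 of the 35 splits, the real one, gave a camera p as small, the highest other -log10 p being 18.05.

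The fall of effector Treg genes was set against dilution of Treg RNA by other cells. Dilution would lower transcripts that all Treg or T cells carry by about the list's median of -1.80. The 12 examined, Foxp3, Il2ra, Il2rb, Lrrc32, Cd3d, Cd3e, Cd3g, Cd4, Cd2, Cd28, Lck and Ptprc, had log2 changes between -0.436 and 0.63. The lowest 95% bound among them was -0.717, which argues against dilution as the cause of a fall of that size. Cd3e, Cd3g, Cd4 and Lck, at -0.39, -0.44, -0.22 and -0.32, had 95% intervals below 0, though none was past the adjusted threshold. Il2ra and Lrrc32 had intervals above 0. A modest dilution is not excluded. A smaller share of effector cells among the sorted Treg, with no change within a cell, stays open and cannot be told apart from lower expression per cell in bulk RNA. Of 76 genes that rose by a log2 of at least 2, 54 are no macrophage or myeloid markers and stayed at 2 or more with the macrophage covariate. On that account alone, a log2 of 2 needs effector cells to be at least 75% of the WT libraries, and larger rises need more. Sema7a would need 86.2% (80.2% at its lower 95% bound), Clstn3 93.8% (84.3%) and Kirrel 99% (96.9%), the last 2 from WT values near 0. A further subset may also have expanded, and the share was not measured.

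Macrophage genes stood higher in the libraries labelled Pdpk1 KO, with 9 of 17 measured markers past the threshold, 0 lower and all 17 with a positive log2 change. The most abundant by group mean were Vcam1, Hmox1 and Csf1r, at 583, 454 and 433 normalized counts, far below Foxp3. The cells were sorted on CD4 and YFP, and whether macrophages passed the sort, free or attached to a Treg, was not measured. Between libraries of a group the markers deviated together, with a median pairwise correlation of 0.702 against at most 0.306 in 1000 random lists of matched level, which is consistent with RNA of macrophages in varying amounts. A lower share of Treg that raises all other types alike would also raise B cell markers. Between the groups their mean differed by a log2 of -0.252 (exact permutation p = 0.4), which does not go with such a rise. The macrophage mean rose over the B cell mean by a log2 of 2.4 (exact permutation p = 0.0286, the smallest possible). The macrophage markers were listed after their rise had been seen, so that p-value is not independent support. The macrophage mean alone overlapped between the groups (exact permutation p = 0.0857), so the size of its difference is uncertain with 4 libraries a group. In WT replicates 1 to 4 it was 3.37, 6.51, 4.51 and 4.68. In replicates 1 to 4 labelled Pdpk1 KO it was 5.85, 8.07, 7.62 and 6.12, higher at each number. The B cell mean was 6.42, 7.16, 7.17 and 6.80 in WT replicates 1 to 4. In those labelled Pdpk1 KO it was 6.05, 6.95, 7.14 and 6.41. Within each group both means were lowest in replicate 1, so the B cell markers varied in part along with the macrophage markers. Equal numbers may or may not pair the libraries, so no paired difference was tested. Whether the genotype or the preparation of the cells sets the amount stays open.

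Calls were somewhat dense around Pdpk1 on chromosome 17. Within 10 Mb, 38 of 295 tested genes were called (10 higher, 28 lower), 12.9% against 9.39% elsewhere (Fisher's exact test, two-sided, p = 0.0552, odds ratio 1.43 with 95% interval 0.982 to 2.02). The share called was 16.1%, 16.8%, 14.3% and 11.4% within 1, 2, 5 and 20 Mb. Within 2 Mb, 16 of 95 tested genes were called (2 higher, 14 lower, Fisher's exact test, unadjusted p = 0.0208). Over the 5 windows tried the smallest adjusted p was 0.0912. Some windows of 10 Mb on chromosome 19 were denser. A segment of another strain carried with the targeted allele may contribute to these calls, but this test leaves it open, since genes next to each other are not independent and few of a segment's genes need to differ.

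Among 93 named genes and 7 library measures, 200 groups of 4 libraries were examined for a value far from the other 3. There were 10, or 5%, and chance gives 5%. In WT, Kirrel was 7.8912 in replicate 1 with the others at 0, Cyp26b1 was 31.616 in replicate 4 (others 16.91 to 17.719) and Maf was 8326.3 in replicate 1 (others 5661.1 to 6111). Pdcd1 was 1749.2 in WT replicate 3 (others 1341.5 to 1358.4), Bcl2 was 8008.1 in WT replicate 2 (others 8713.8 to 8801) and Cd22 was 108.22 in WT replicate 1 (others 36.824 to 37.523). In the libraries labelled Pdpk1 KO, Cyp26b1 was 268.14 in replicate 1 (others 136.97 to 156.06). In replicate 3 of that group Klrg1 was 48.276 (others 6.5174 to 12.054), Il18r1 was 772.42 (others 711.73 to 721.03) and Nop56 was 3607.2 (others 3903.9 to 3951.2).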

How the results depend on the processing

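Alternatives that use macrophage markers, GC content or distance to Pdpk1 were chosen after seeing the data. Under the pseudocounts, filters, TMM, quantile normalization, quality weights, edgeR, DESeq2 and the GC and length correction, counts of genes stayed within 1.5 times of 611 higher and 700 lower. Of the 1311 calls, between 1190 and 1309 were kept under each. With an absolute log2 change of at least 1 there were 154 and 327. Without genes within 20 Mb of Pdpk1, 593 genes were higher and 666 lower. Leaving out 1 library gave 389 (without WT replicate 4) to 588 higher and 495 to 724 lower genes and 13 or 14 lists, with 395 higher without replicate 3 labelled Pdpk1 KO, and between 851 and 1097 of the 1311 calls were kept. Fewer samples enter those fits. Lists numbered 13 to 15 under all settings except an estimated correlation, which left 8. The 13 of fry differ from those of camera. Ribosomal proteins, interferon and myeloid markers did not pass in fry (adjusted p = 0.0858, 0.165 and 0.108), while fatty acid synthesis, ERK feedback and cell death did (0.0472, 0.0367 and 0.0367).

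With the macrophage mean as a covariate, 213 genes were higher and 280 lower. Without the 3 libraries highest in these markers the counts were 167 and 305. The direction was kept by 1310 and 1311 of the 1311 calls. The median absolute log2 change of these calls went from 0.745 to 0.716 and 0.769 and the median SE from 0.151 to 0.203 and 0.196. Larger errors and, for part of the genes, smaller changes ended calls. Of the 92 named genes besides Pdpk1, 36 lost their call with the covariate. Pik3ip1 was at 0.38, Bbc3 at 0.17, Egr3 at -0.38, Acsl3 at 0.32, Rpl5 at 0.32, Igsf9b at -2.66, Il10 at -2.90 and Gjb2 at -3.82. Others that lost it were Dkc1, Rpl3, Rpl10a, Rps6, Slc38a2, Slc7a5, Slc16a3, Eno1, Ebp, Fasn, Gclc, Nfe2l2, Fcgr3, Lyz2, Csf1r, Pecam1 and Dusp1. Of these, Fasn (0.565), Slc16a3 (-1.11), Ebp (-0.55), Gclc (0.59), Nfe2l2 (0.441), Pecam1 (0.459) and Dusp1 (-0.61) had changes as large as without the covariate. Slc38a2 was nearly unchanged, at 0.511 against 0.513. Pcsk1, Sgk3, Prkcq, Tyms, Birc5, Mcm5, Rrm2 and Cd22 lost their call as well. Without the 3 libraries 31 lost it, Bcl2 and Nob1 among them (adjusted p = 0.0617 and 0.0644). Csf1r and Adgre1 of the myeloid list are also among the markers that form the covariate. With the covariate Csf1r went from 2.436 to 0.014, while Fcgr3 and Lyz2 went from 3.139 and 2.875 to 2.264 and 2.536. The myeloid list's median was -0.591 with the covariate (camera adjusted p = 0.664) and 0.351 without the 3 libraries (camera adjusted p = 0.0531). The other 12 lists stayed past the threshold under both, but with the covariate the median went from 0.459 to 0.18 for ribosomal proteins, -0.788 to -0.36 for cell cycle, 0.492 to 0.262 for naive and central markers, 0.424 to 0.245 for FoxO1 targets and 0.293 to 0.639 for interferon. Without the 3 libraries these medians were 0.346, -0.864, 0.403, 0.361 and 0.61.

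Same-numbered libraries deviated together with correlations of 0.217, 0.0921, 0.0481 and 0.113, so the numbers were not taken to pair the libraries. With a replicate block, 1243 genes were higher and 1292 lower, 14 lists passed, the 1311 calls were all kept and the log2 change of Pdpk1 was -0.17 (adjusted p = 0.145). At each number Pdpk1 was lower and the macrophage mean higher in the library labelled Pdpk1 KO. Of the 8 libraries, 6 correlated best with their own number in the other group. WT replicate 3 and replicate 2 labelled Pdpk1 KO did not, so pairing is not excluded. The cause was not tested.

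Pdpk1 stayed between -0.29 and -0.08 in every setting, never past the threshold (adjusted p from 0.145 to 0.904), and without 1 library between -0.2885 and -0.0896. Values near 0 changed sign without being called. Foxp3 ranged from -0.0092 to 0.1662 over single libraries left out, Cox4i1 from -0.0530 to 0.1735, Fth1 from -0.1966 to 0.0600, mt-Co1 from -0.0123 to 0.1493 and mt-Cytb from -0.0127 to 0.2447. With the macrophage covariate Cox4i1 was -0.1935, Sdha -0.0113, mt-Co1 -0.1352, mt-Cytb -0.1859 and Xist 0.2393. Without the 3 libraries mt-Co1 was -0.0550 and mt-Cytb -0.0903, and under quantile normalization mt-Cytb was -0.0843. For these sign changes the cause was not tested. At this depth, with 4 libraries a group, 42% of simulated genes changed 1.5-fold and 66% of those changed 2-fold were recovered.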

Other observations

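The gene families and the emigrant hypothesis below were chosen after the data had been seen, so no tests of the families are given, while 5 emigrant markers had not been looked at before their test. All 3 Pim genes, which encode growth-promoting kinases induced by cytokines, were higher. Pim2 went from 923 ± 125 to 2294 ± 172 normalized counts, Pim1 from 6587 ± 1230 to 10518 ± 993 and Pim3 from 714 ± 110 to 1103 ± 65.8 (SD, n = 4 each). Of 12 genes with symbols of translation elongation factors, Eef1b2, Eef1e1, Eef1g, Eef2 and Eef2k were higher. Eef2k, which encodes a kinase of the elongation factor eEF2, and Eef1e1 match by symbol only and are not elongation factor genes. Of 54 genes with symbols of initiation factors 7 were higher and 0 lower. Of 7 importin genes, Ipo4, Ipo5 and Ipo7 were higher, and of 11 guanylate-binding protein genes 4 were higher and 1 lower.

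Tested NAIP genes, which encode sensors of bacterial proteins and are close copies of each other, were all lower, Naip2 from 304 ± 88.9 to 71.1 ± 10.8, Naip5 from 165 ± 36.0 to 23.2 ± 15.3 and Naip6 from 162 ± 104 to 18.6 ± 8.48 normalized counts. Of 10 semaphorin genes, Sema4a, Sema4b, Sema4d and Sema4f were lower while Sema7a rose. Of 29 interleukin receptor genes 7 were lower, with Il1rl1, which encodes the interleukin 33 receptor, from 364 ± 101 to 31.3 ± 9.73 and Il9r from 244 ± 67.1 to 54.4 ± 27.9, whereas Il2ra, Il7r and Il17ra rose. Of 7 TNF superfamily genes 3 were lower, among them Tnfsf11, which encodes RANKL, from 848 ± 162 to 324 ± 11.3, while Tnfsf8 rose from 1601 ± 224 to 2665 ± 234. Of 16 TNF receptor genes Tnfrsf1b, Tnfrsf4, Tnfrsf8 and Tnfrsf9 were lower and Tnfrsf26 higher, and of 4 S100 genes S100a6 and S100a11 were lower.

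Cd24a, Dntt and Sox4, genes of immature T cells, were higher in the libraries labelled Pdpk1 KO, at log2 changes of 1.54, 1.60 and 0.94. A hypothesis was that recent thymic emigrants may form a larger part of the sorted cells. Of 5 emigrant markers not looked at before, 3 were among the tested genes, while Rag1 and Rag2 were not. Of these 3, 0 passed in the direction that emigrants show. Plxnd1 was at -0.45 where a rise would be needed, and H2-Q7 and H2-Q4 were at -0.17 and -0.12 where a fall would be. The last 2 lie in the needed direction without passing. Among markers seen before, Ccr9 was at -0.31 where a rise would be needed, and did not pass (adjusted p = 0.505). H2-Q6 was lower as in emigrants (-0.49, adjusted p = 0.0167), whereas Il7r and Bcl2, which are low in emigrants, rose by 1.42 and 0.58. Il7r is also a listed FoxO1 target, and both genes are listed naive and central markers, so their rises need not bear on emigrants. The markers not seen before gave no support for the hypothesis. With 3 tested, among them 2 H2-Q genes whose values are uncertain, they do not decide it, and a contribution of emigrants is not excluded.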
